A study of Mus musculus with 8 samples.

How the data were processed

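The series holds ATAC-seq libraries, which mark DNA that a transposase can reach and so map open chromatin, from c-Kit+ mouse bone marrow cells of 4 genotypes. Per the labels, marrow of individual mice was selected for c-Kit (Cd117) with antibody-coupled magnetic beads, 50000 cells were used per sample, and the cells were taken 4 weeks after injection of PIpC, which switches on the Mx1-Cre recombinase. Each genotype had 2 libraries. The labels speak of individual mice and do not say outright that the 2 libraries of a genotype came from different animals, so p-values measure the spread between these libraries.

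The deposited files are peak lists, 1 per library, so peaks were not called on pooled replicates. Each list has 6 columns with no header, gives chromosome, start, end, a peak name, a score and a strand that is always plus, and carries no read number. The score is the authors' own value for a peak, deposited between 0.99 and 1 with 27.2% to 34.9% of each library's peaks at exactly 1. What the score measures is not given in the sources used here. It served only to rank or filter peaks within a list. The submitters' processing notes name Bowtie, without a version, and the mm9 mouse build. The peak caller, its settings, the handling of the transposase offset, of duplicate reads and of reads that match several places are not given in the sources used here. The largest peak end on chromosome 1, 197090546, lies past the largest gene end of 195291439 in the gene table at hand, which is for GRCm38, so the peaks are not in GRCm38 coordinates.

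No mm9 genome or annotation was used here, and coordinates were not moved between builds. Promoter shares, gene lists, cell type markers, the loci planned by name and motif content were therefore not analysed here, and regions are named by mm9 coordinates (from 1) with no gene, exon or intron assigned. A model of read counts was planned for the case that the files held counts on shared regions, and was not run because they hold peak lists.

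Groups follow the title and the genotype label, which name the same genotype for each library except that the combined genotype reads Smc3 fl/del in the genotype label and Smc3 heterozygous in the title. It is called Smc3-deleted Flt3-ITD here. The free-text descriptions of the Flt3-ITD libraries and of the Smc3 del/+ libraries are exchanged relative to title and genotype. Exchanging both groups was run as an alternative.

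All 557040 peaks were merged into union regions where they overlapped by at least 1 bp, and 1550 repeated intervals within lists (0.278%) merged with them. A region counted as called in a library when a peak of that library lay in it. For each genotype pair, a region was gained when called in both libraries of the first genotype and neither of the second, and lost in the reverse case. With 2 libraries against 2 the smallest two-sided permutation p is 0.333, so no p is given for a pair. The count was set beside those for the 2 other ways to split the same 4 libraries. Across all 8 libraries, a region separated 2 sides when called in all 4 libraries of one side and none of the other. This was done for Smc3 deletion, for Flt3-ITD and for the interaction, which sets control and Smc3-deleted Flt3-ITD against the single genotypes. Counts were set beside all 35 splits into 4 and 4.

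Numbers of peaks, bases covered, median width, the X share and Y peaks were compared for the same 3 contrasts by an exact two-sided permutation test of the difference of means over 70 assignments, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over 15 tests. Similarity of libraries was the Jaccard index of bases covered, with an exact one-sided test over the 105 ways to form 4 pairs, whose smallest p is 0.00952. Gathering of regions in 1 Mb windows was tested with the hypergeometric distribution among the regions that could have passed, with Benjamini-Hochberg adjustment over windows. Intervals for shares are exact (Clopper-Pearson, 95%) and cover counting error only. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

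The rule for named regions was fixed before the data were examined: for each pair, the 3 gained and the 3 lost regions with the highest mean percentile of score within the libraries that called them. Scores of exactly 1 tie, and peak width then decided. Regions named for the contrasts over all 8 libraries were ranked in the same way, but were added after their values were seen.

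The merging and counting steps were tested on simulated data of 20000 regions with 200 planted changes per direction. Between 63% and 70% of planted regions passed the rule for the contrasts over 8 libraries and between 78% and 83% for the pairs, since a call was sometimes missed in a library. These shares follow from the call probability set for the planted regions, which was not estimated from these libraries. They do not measure the sensitivity of the rules in the real data. Of the 17800 regions simulated without a change, each direction of the contrasts over 8 libraries also called between 9 and 34, and the rule for a pair called between 301 and 686, more than the 156 to 166 planted regions it recovered. Counting the regions planted for other comparisons as well, between 717 and 1113 regions not planted for the pair were called. Unchanged regions were drawn from all union regions, and their call rates came from the 8 libraries pooled, scaled for each library. Real differences between genotypes thus entered as missed calls, so these counts do not measure false calls in the real data. The number of reads per library is unknown, so a region without a peak can be open below the limit of detection, and no interval that needs depth is given.

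Alternatives fixed before the data were examined were the upper 50% of each list by score, an equal number of peaks per library (the 61953 best by score, the length of the shortest list), an overlap of at least 50% of the shorter interval, each replicate left out in turn, autosomes only, permutation within replicate numbers and the exchanged groups. For the overlap of 50%, a peak joined a region only when it overlapped it by that share. Added after seeing the data were absence defined as no peak within 1 kb, only peaks with a score of exactly 1, and leaving out both Smc3-deleted Flt3-ITD libraries.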

Results

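Chromatin accessibility was profiled by ATAC-seq in c-Kit+ bone marrow cells, a fraction that holds hematopoietic stem and progenitor cells, of mice in 4 genotypes with 2 libraries each. Smc3 encodes a core subunit of cohesin, the ring complex that holds sister chromatids together and shapes chromatin loops. Flt3-ITD is an activating internal tandem duplication of the receptor tyrosine kinase Flt3 found in acute myeloid leukemia. Control mice carried a floxed Smc3 allele without Mx1-Cre. Smc3 del/+ mice had lost 1 Smc3 allele, Flt3-ITD mice carried the duplication, and Smc3-deleted Flt3-ITD mice carried a Smc3 deletion with Flt3-ITD. The labels of the last name both Smc3 fl/del and Smc3 heterozygous, so the state of their second Smc3 allele is not settled. The series asks how cohesin dose acts in normal and malignant blood formation. The free-text descriptions of the Flt3-ITD and Smc3 del/+ libraries are exchanged relative to their titles and genotype labels. Every statement on either single genotype therefore rests on the title and genotype label.

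Smc3-deleted Flt3-ITD libraries held the most peaks, 80507 ± 270 (SD, n = 2), and both lay above all 6 other libraries. Control libraries held 69651 ± 6893 (SD, n = 2), Flt3-ITD libraries 65685 ± 2075 (SD, n = 2) and Smc3 del/+ libraries 62677 ± 1024 (SD, n = 2). Relative to control, the mean was 15.6% higher in the combined genotype and 10.0% lower in Smc3 del/+, and both Smc3 del/+ libraries (61953 and 63401 peaks) lay below both control libraries (74525 and 64777). Peaks covered 36.5 ± 3.47 Mb in control (34.1 and 39.0 Mb, a range that holds every single-genotype library), 36.8 ± 0.486 Mb in Smc3 del/+, 37.3 ± 1.14 Mb in Flt3-ITD and 41.6 ± 0.175 Mb in Smc3-deleted Flt3-ITD (SD, n = 2). In the exact permutation tests over 8 libraries, differences in peak number did not pass for Smc3 deletion (difference of means 3924, p = 0.514) or for Flt3-ITD (6932, p = 0.2). The former ran from 889 without Smc3-deleted Flt3-ITD replicate 1 to 7137 without Smc3 del/+ replicate 1, and the latter from 4398 without Smc3-deleted Flt3-ITD replicate 1 to 9891 without Flt3-ITD replicate 2. For the interaction, which sets control and Smc3-deleted Flt3-ITD against the single genotypes, the difference was 10898 (exact p = 0.0571). Read depth is unknown for every library, so a difference in peak number cannot be separated from one in sequencing.

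Peaks were narrower in control (median width 408.5 ± 0.707 bp) and Smc3-deleted Flt3-ITD (406.5 ± 0.707 bp) than in Flt3-ITD (423 ± 1.41 bp) and Smc3 del/+ (433 ± 1.41 bp; SD, n = 2 each). The interaction difference of -20.5 bp had the smallest exact p the permutations can give, 0.0286, with every library of one side below every library of the other. It did not pass after Benjamini-Hochberg adjustment over 15 tests (0.214).

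Sex chromosomes set the Smc3-deleted Flt3-ITD libraries apart. Their lists had 288 ± 8.49 peaks on Y, against 93.5 ± 6.36 in control, 91.5 ± 7.78 in Flt3-ITD and 84.5 ± 0.707 in Smc3 del/+ (SD, n = 2 each). X held 2.66% ± 0.0818 of their peaks, against 3.49% ± 0.00304 in control, 3.58% ± 0.0280 in Smc3 del/+ and 3.72% ± 0.0960 in Flt3-ITD (SD, n = 2 each). On each of the 19 autosomes the combined genotype had 1.17 to 1.30 times the mean peak number of the other 6 libraries, against 0.904 times on X (1.06 times outside X 120 to 123 Mb) and 3.21 times on Y. The first 1 Mb of Y held 56 regions called in both Smc3-deleted Flt3-ITD libraries, and 55 of them were called in no other library; 5 other regions there were called in the other 6 libraries and in neither of these. From 1 to 2 Mb and from 2 to 3 Mb of Y, 51 and 28 regions were called in both its libraries alone, but 25 and 17 were called in the other 6 libraries and in neither of these. The windows on Y, X and chromosome 3 were chosen after their values were seen. At X 120 to 123 Mb the picture was the reverse: between 219 and 321 regions were called in each of the other 6 libraries, and 5 and 3 in those of the combined genotype. A tract on chromosome 3 from 25416099 to 25455120 held 8 regions called in the other 6 libraries and in neither library of the combined genotype. The labels do not give the sex of the mice, so every comparison with this genotype also compares libraries that differ on the sex chromosomes.

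**Figure D1:**
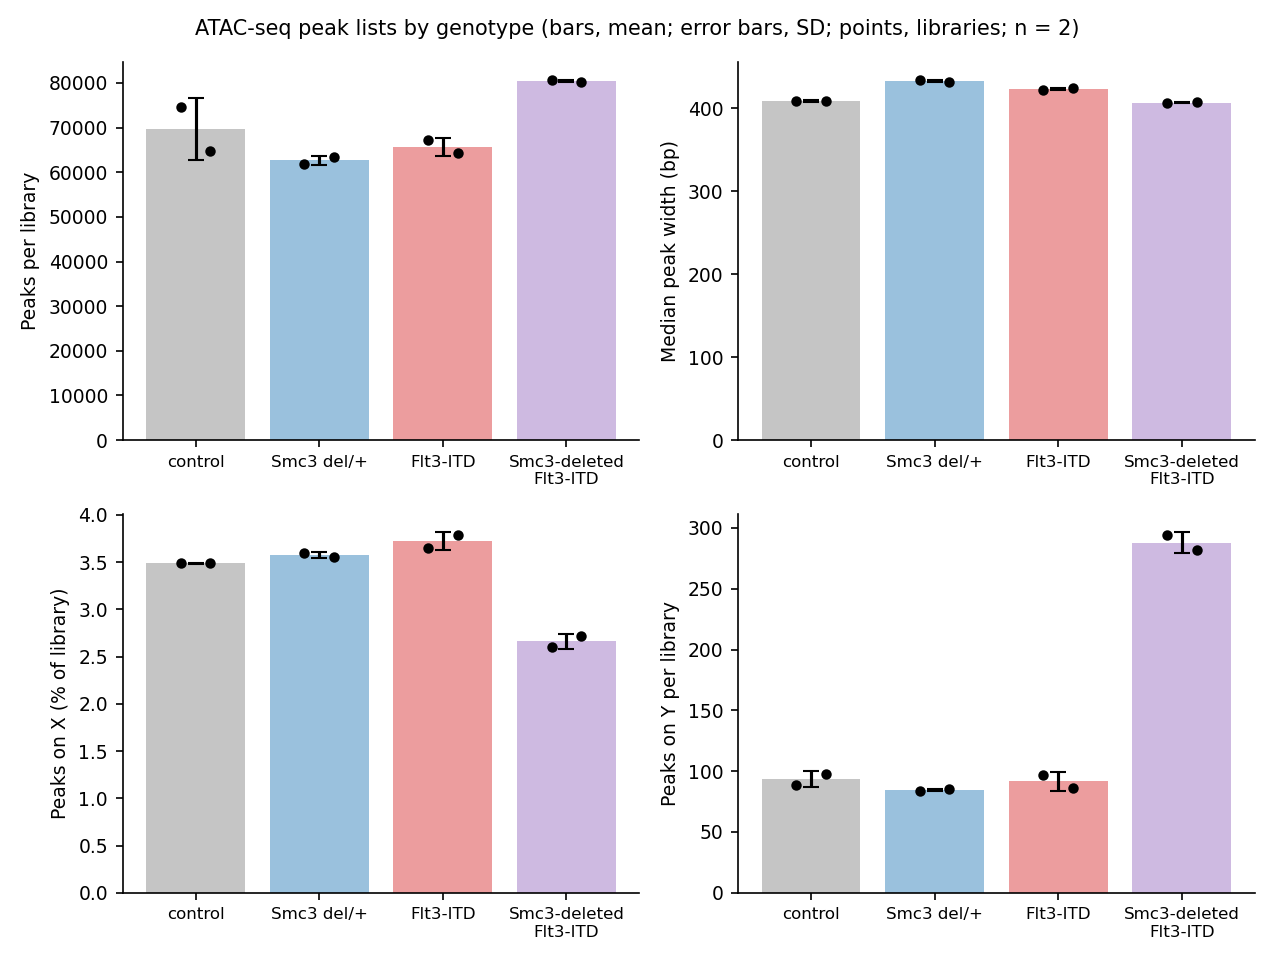
Number of peaks, median peak width (bp), share of peaks on X (%) and number of peaks on Y for each genotype; bars are means, error bars SD and points the 2 libraries. Smc3-deleted Flt3-ITD stands at 80507 peaks and 288 Y peaks, above the 3 other genotypes, and at 2.66% on X, below them.

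Libraries of the same genotype shared more of their accessible bases than libraries of different genotypes. The Jaccard index was 0.358 ± 0.00901 over the 4 pairs within a genotype and 0.313 ± 0.0169 over the 24 pairs between genotypes (SD), a difference of 0.0453 (exact one-sided p = 0.00952, the smallest the pairings can give). Smc3-deleted Flt3-ITD was nearest to Flt3-ITD (0.320 ± 0.00413, SD over 4 library pairs), then to control (0.306 ± 0.00518), and farthest from Smc3 del/+ (0.281 ± 0.00198). Smc3 del/+ and Flt3-ITD each stood at the same distance from control within their spread (0.329 ± 0.00102 and 0.328 ± 0.00236), and lay farther from each other (0.312 ± 0.00118). Without both Smc3-deleted Flt3-ITD libraries, a removal chosen after seeing the data, the difference was 0.0313 with an exact p of 0.0667, the smallest that 6 libraries allow.

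**Figure D2:**
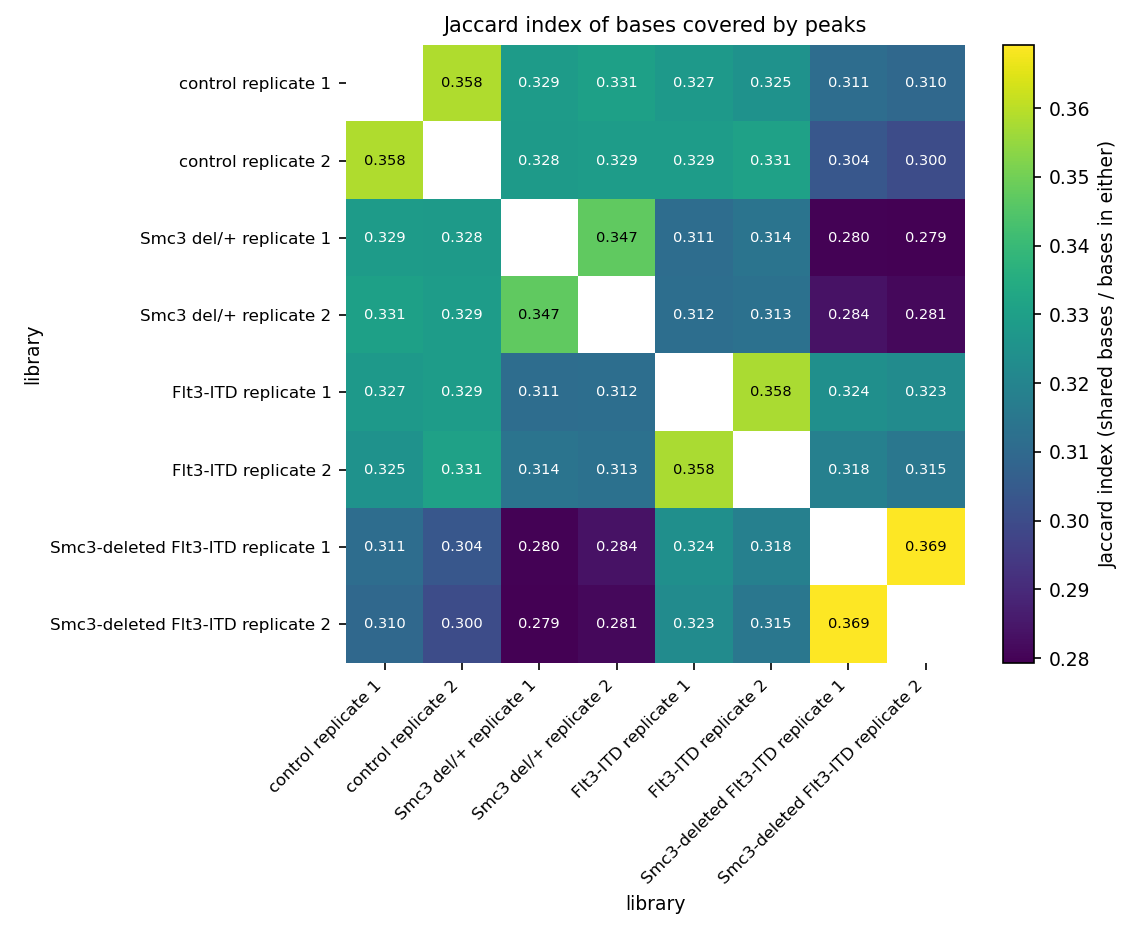
Jaccard index (shared bases divided by bases in either library) for each pair of the 8 libraries, 2 per genotype, as a colour scale with the value in each cell. The 4 pairs within a genotype lie between 0.347 and 0.369, and the 24 pairs between genotypes lie between 0.279 and 0.331.

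Merging gave 114533 union regions with a median width of 905 bp. Of these, 36101 (31.5%) were called in all 8 libraries and 27458 in a single library. In 48864 regions both libraries of every genotype gave the same call. Among those that varied, 5213 were called in Smc3-deleted Flt3-ITD alone, 1426 in every genotype but Smc3 del/+, 1310 in control and Smc3 del/+, and 1008 in Flt3-ITD and Smc3-deleted Flt3-ITD. Calls made in control alone numbered 724, in Smc3 del/+ alone 676 and in Flt3-ITD alone 389. Control and Smc3-deleted Flt3-ITD shared 403 regions absent from both single genotypes, whereas the single genotypes shared 48 absent from the other genotypes. The former lists were longer on average (75079 against 64181 peaks), so this imbalance cannot be told from list length. A split with control replicate 1, Flt3-ITD replicate 1 and both Smc3-deleted Flt3-ITD libraries on one side gave 434 and 21.

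Smc3 del/+ against control was the comparison for losing 1 Smc3 allele. Control mice had no Mx1-Cre, so the recombinase may differ along with the allele, and this comparison cannot tell them apart. Smc3 del/+ cells lost 4861 regions and gained 1827 of the 60423 regions called in both libraries of either genotype. In simulated lists the rule for a pair also called between 301 and 686 of 17800 unchanged regions. A pair count can thus hold regions that differ by missed calls alone. The simulation does not give their share, since its regions came from the whole union and its call rates from all libraries pooled. The highest-ranked gained regions lay at chromosome 7:29159664-29161266, chromosome 10:68675446-68676903 and chromosome 19:6399159-6400665. That on chromosome 7 was also called in both Flt3-ITD libraries and in neither Smc3-deleted Flt3-ITD library, and no control library had a peak within 1 kb of it. On chromosomes 10 and 19, both control libraries had a peak within 1 kb, outside the region itself. The highest-ranked lost regions lay at chromosome 5:134788958-134790219, chromosome 9:16020439-16021584 and chromosome 3:143864405-143865658. Those on chromosomes 5 and 9 were kept in both Flt3-ITD libraries, and both Smc3 del/+ libraries had a peak within 1 kb. Around the region on chromosome 3, no Smc3 del/+ library had such a peak. Both directions together gave 6688 regions, against 3120 in the higher of the other splits of these 4 libraries, but the 1827 gains alone lay below the 2339 that a single direction reached in those splits. With an equal number of peaks per library the gained share rose from 27.3% to 45.5% (2771 gained). Leaving out a library loosens the rule, and gave 3035 regions gained without control replicate 2 and up to 6664 without Smc3 del/+ replicate 1.

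Flt3-ITD against control was the comparison for the duplication without Smc3 deletion. The genotype label of the Flt3-ITD mice names no Cre and no floxed Smc3 allele, so these may differ from control as well. Flt3-ITD cells lost 4852 regions and gained 2734 of 61836. The highest-ranked gained regions lay at chromosome 7:29159664-29161266, chromosome 8:74845892-74847186 and chromosome 16:10990972-10992807. Those on chromosomes 7 and 8 were called in both libraries of both single genotypes and in no control or Smc3-deleted Flt3-ITD library. Near the region on chromosome 8, 1 control library had a peak within 1 kb, and near that on chromosome 16 both did. The highest-ranked lost regions lay at chromosome Y:2857065-2858477, chromosome 11:30082161-30083466 and chromosome 7:90801599-90803100, and at all 3 both Flt3-ITD libraries had a peak within 1 kb. The region on chromosome 11 was called in both Smc3-deleted Flt3-ITD libraries. Both directions together gave 7586 regions, against 2876 in the higher of the other splits. With an equal number of peaks 3315 regions were gained and 3900 lost, and the gained share rose to 45.9%. Leaving out Flt3-ITD replicate 2 gave 8662 regions gained, and leaving out control replicate 2 gave 14081 lost.

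Regions gained or lost against control with the Flt3-ITD single genotype were followed into the libraries not used to find them. Of the 2734 gained regions, 69.9% ± 1.24 (SD, n = 2) were called in Smc3-deleted Flt3-ITD libraries and 25.5% ± 1.68 in Smc3 del/+ libraries. Of the 4852 lost regions, 36.7% ± 0.714 were called in Smc3-deleted Flt3-ITD and 55.8% ± 2.07 in Smc3 del/+ (SD, n = 2). Over all 61836 regions of this comparison the shares were 87.2% ± 0.375 and 79.1% ± 0.608. The difference for gained regions was 44.4 percentage points, 42.3 with the upper 50% of each list by score and 27.5 with equal peak numbers. For lost regions it was -19.2 percentage points, -0.926 with the upper 50%, -37.9 with equal peak numbers and 31.6 with scores of exactly 1, a limit chosen after seeing the data, so its direction depends on the peaks that enter. For the 1827 regions gained in Smc3 del/+, 42.9% ± 1.01 were called in Smc3-deleted Flt3-ITD and 31.9% ± 2.13 in Flt3-ITD, and with equal peak numbers this difference turned to -3.54 percentage points. For the 4861 regions lost in Smc3 del/+, 64.3% ± 1.54 were called in Smc3-deleted Flt3-ITD and 54.0% ± 2.66 in Flt3-ITD, which turned to -5.34 percentage points with equal peak numbers. Over all 60423 regions of this comparison the shares were 85.2% ± 0.353 and 81.7% ± 1.07. All of these sets were chosen with the same control libraries, so the shares are not independent of them.

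Smc3-deleted Flt3-ITD against control joined both changes, and Mx1-Cre may differ here as well. Cells of this genotype gained 10253 regions and lost 4346 of 72432. The highest-ranked gained regions lay at chromosome Y:2132020-2134032, chromosome 11:3230182-3231455 and chromosome 3:51512348-51514082. That on chromosome 3 was also called in both Flt3-ITD libraries, and both control libraries had a peak within 1 kb of that on chromosome 11. The highest-ranked lost regions lay at chromosome X:122695372-122699300, chromosome X:5136339-5138075 and chromosome 3:84575141-84576699. The regions at X:5136339 and on chromosome 3 were called in all 6 libraries of the other genotypes. On autosomes the counts were 9857 gained and 3843 lost. Of the 4346 lost regions, 60.0% ± 0.374 were called in Smc3 del/+ libraries and 31.2% ± 1.03 in Flt3-ITD libraries. Of the 10253 gained regions, 29.6% ± 3.44 were called in Flt3-ITD and 12.4% ± 0.883 in Smc3 del/+ (SD, n = 2 each). Over all 72432 regions the shares were 75.1% ± 1.64 in Flt3-ITD and 69.8% ± 0.732 in Smc3 del/+. The difference for lost regions, -28.8 percentage points (Flt3-ITD minus Smc3 del/+), was -7.49 with the upper 50% of each list by score and 13.6 with scores of exactly 1. Both directions together gave 14599 regions, against 2237 in the higher of the other splits. With an equal number of peaks 6430 regions were gained and the gained share fell from 70.2% to 54.8%. Without Smc3-deleted Flt3-ITD replicate 2 the gains were 18654, and without control replicate 2 the losses were 12020.

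Adding Smc3 deletion to Flt3-ITD was read from Smc3-deleted Flt3-ITD against Flt3-ITD, where Mx1-Cre may differ as well. The combined genotype gained 9018 regions and lost 2055 of 69342. The highest-ranked gained regions were chromosome Y:2132020-2134032, chromosome Y:2037118-2038502 and chromosome 17:88145150-88146803, and that on chromosome 17 was called in every library but those of Flt3-ITD. Lost regions ranked highest at chromosome Y:2891331-2893248, chromosome 16:59246252-59248972 and chromosome X:122687030-122688919, each called in all 6 libraries of the other genotypes. Without the sex chromosomes 8694 regions were gained and 1591 lost. Both directions together gave 11073 regions, against 2310 in the higher of the other splits. With an equal number of peaks the counts were 4216 gained and 3455 lost, and the gained share fell from 81.4% to 55.0%. Without Smc3-deleted Flt3-ITD replicate 2 the gains were 17727, and without Flt3-ITD replicate 2 the losses were 6430.

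Adding Flt3-ITD to Smc3 deletion gave the largest of the 5 pair counts, with 14087 regions gained and 4249 lost of 71389 in Smc3-deleted Flt3-ITD against Smc3 del/+. The second Smc3 allele of the combined genotype is not settled by the labels, so Smc3 dose may differ as well. This pair also holds the longest and the shortest lists on average (80507 and 62677 peaks). Gained regions ranked highest at chromosome Y:2132020-2134032, chromosome 9:50852259-50853710 and chromosome 17:73375314-73377557. Those on chromosomes 9 and 17 were called in all libraries but those of Smc3 del/+. The highest-ranked lost regions lay at chromosome X:122695372-122699300, chromosome X:121444596-121446376 and chromosome X:121925140-121928029, within the X tract described above. Autosomes held 13633 of the gained and 3804 of the lost regions. Both directions together gave 18336 regions, against 1876 in the higher of the other splits. With an equal number of peaks 7612 regions were gained and the gained share fell from 76.8% to 55.6%. Without Smc3-deleted Flt3-ITD replicate 2 the gains were 23320, and without Smc3 del/+ replicate 1 the losses were 9258.

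**Figure D3:**
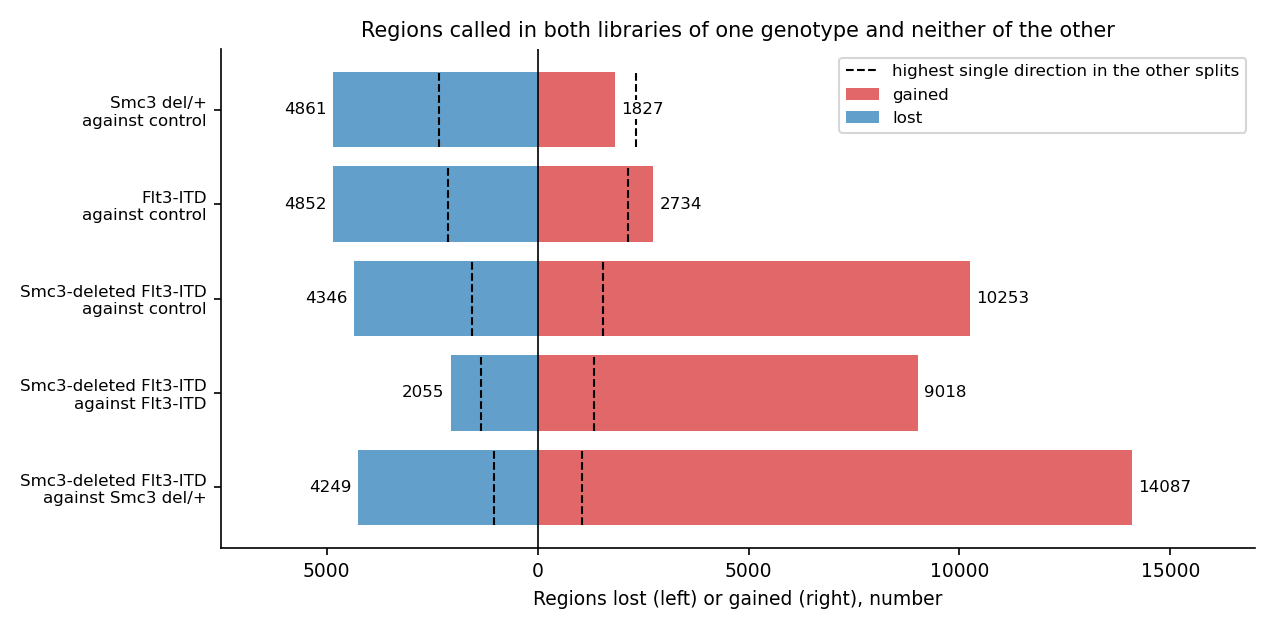
Number of regions called in both libraries of the first genotype and neither of the second (gained, right) or the reverse (lost, left) for 5 genotype pairs with 2 libraries per genotype; dashed lines mark the highest count in a single direction for the other splits of the same 4 libraries. The bars reach from 1827 to 14087 gained and from 2055 to 4861 lost, and the 1827 gained regions of Smc3 del/+ lie below the dashed line at 2339.

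Among the 35 splits of the 8 libraries into 4 and 4, the split by Flt3-ITD separated the most regions. In total 2318 regions were called in all 4 libraries with Flt3-ITD and none without (1008) or the reverse (1310), and the highest of the other 34 splits gave 455. Unequal sides were not counted in this way; Smc3-deleted Flt3-ITD against the other 6 libraries gave 5213 regions called there alone and 507 called in all others. Called with Flt3-ITD were chromosome 3:127495805-127496365, chromosome 2:25050154-25050588 and chromosome 7:54270229-54270601. Absent with Flt3-ITD were chromosome 8:131212248-131213443, chromosome Y:2875920-2876652 and chromosome 14:58364409-58365114. The regions on chromosomes 3 and 8 had no peak within 1 kb in any library of the other side, whereas those at chromosome 7 and chromosome 14 had one in all 4. Of the separating regions, 2.85% lay on X or Y. Equal peak numbers gave 2321 regions against a highest other split of 362, which was that by Smc3 deletion. Autosomes alone gave 2252 against 437. Leaving out both Smc3-deleted Flt3-ITD libraries, which loosens the rule, gave 3839 regions for Flt3-ITD against the rest and 2972 for Smc3 del/+ against the rest. Without Flt3-ITD replicate 2 the count was 3689.

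Smc3 deletion separated the libraries at 345 regions, 152 called with the deletion and 193 without. Of the 35 splits 4 gave as many, among them those by Flt3-ITD and the interaction. The top regions called with the deletion lay at chromosome 12:103605492-103605943, chromosome 11:6174596-6175052 and chromosome 5:134790440-134791622, and all 4 libraries without the deletion had a peak within 1 kb of each. Those called without it lay at chromosome 12:103521053-103522119, chromosome 1:88369533-88369956 and chromosome 12:103606136-103606973, where 4, 1 and 4 libraries with the deletion had a peak within 1 kb. The interaction gave 451 regions, and 3 of the 35 splits gave as many, that by Flt3-ITD among them. Of the 451, 403 were called in control and Smc3-deleted Flt3-ITD and 48 in the single genotypes. Chromosome 16:20622387-20623369, chromosome X:93152497-93152972 and chromosome 2:91805825-91806297 were the top regions of the former set, with such a peak in 4, 4 and 2 libraries of the other side. Chromosome 7:29159664-29161266, chromosome 8:74845892-74847186 and chromosome 4:118905542-118906028 were those of the latter, with one in 0, 1 and 4. Of the 42 distinct regions named for the pairs and contrasts, 24 no longer pass when absence means no peak within 1 kb, a rule chosen after seeing the data. Under the groups of the free-text descriptions the counts for Flt3-ITD and for Smc3 deletion trade places, 345 and 2318. Without Smc3 del/+ replicate 1 the count for Smc3 deletion was 725, and without control replicate 2 that for the interaction was 1256.

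**Figure D4:**
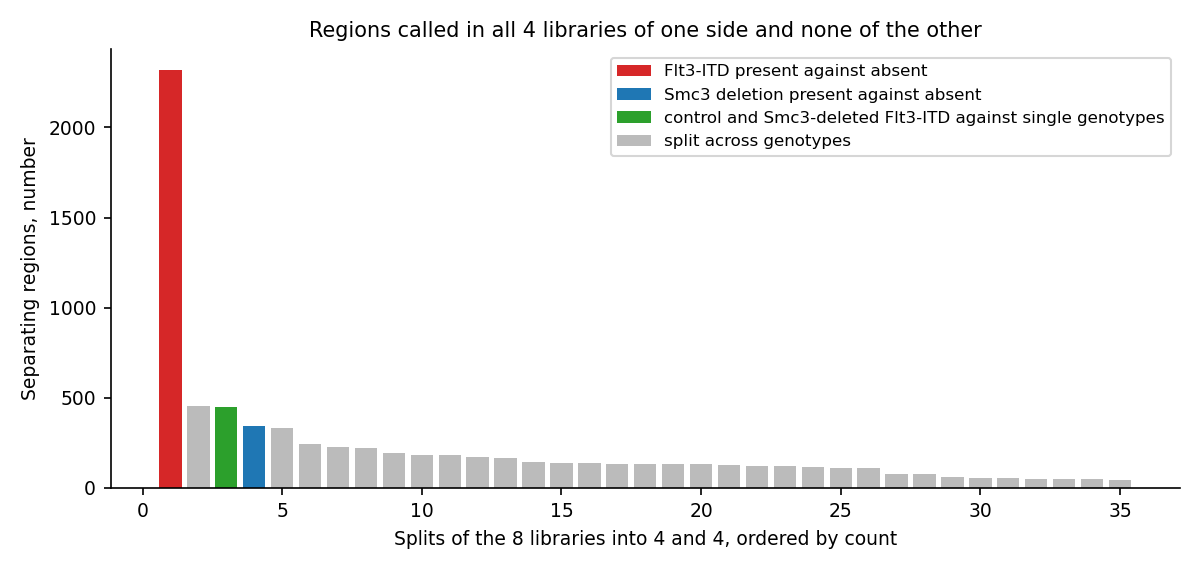
Number of regions called in all 4 libraries of one side and none of the other, for the 35 splits of the 8 libraries into 4 and 4, ordered by count; colours mark the 3 splits that follow genotype. Flt3-ITD gives 2318 regions, the highest other split 455, the interaction 451 and Smc3 deletion 345.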

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

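The tests with equal peak numbers for peak width and for the Flt3-ITD separation, and the test for sex in that separation, were set before their results were seen; the other tests in this part were chosen after.

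Smc3 deletion went with fewer peaks in the absence of Flt3-ITD and more in its presence: the mean was lower by 6974 in Smc3 del/+ against control (a change of -6974) and higher by 14822 in Smc3-deleted Flt3-ITD against Flt3-ITD, with every library on the stated side. The former change rests in part on control replicate 1, without which it was -2100. On autosomes the changes were -6777 and 14925. The changes over all peaks enter the interaction contrast, a difference of 10898 between means over 4 libraries per side (exact permutation p = 0.0571). Its scale is smaller than that of the plain difference of the changes. Median peak width went the other way, by 24.5 bp without Flt3-ITD and by -16.5 bp with it (exact permutation p = 0.0286 for the interaction, 0.214 after adjustment over 15 tests). A different set of sites is not the cause alone: at the 36101 regions called in all 8 libraries, the mean of the widest peak differed by -75.6 bp in control and Smc3-deleted Flt3-ITD (531 ± 7.78 bp against 607 ± 13.2 bp in the single genotypes, SD, n = 4), and its median by -25.5 bp. Nor does the number of peaks account for it, since the median widths differed by -22.5 bp with equal peak numbers. Differences in fragment length or read depth between libraries, which may act on width, and the genotype itself stay open, as the files hold no reads.

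Y peaks were counted in all libraries although the comparisons are about genotype, and reached a mean of 288 in Smc3-deleted Flt3-ITD. Male mice in this genotype and female mice in the others could explain the regions that both its libraries called in the first 1 Mb of Y, a window chosen after its values were seen: 98.2% of them were called in no other library. A Y present in these mice and absent in the others does not by itself account for 47 regions in the first 3 Mb of Y. The other 6 libraries called them and neither of these did, and 5 of them lie in the first 1 Mb. How reads that match several places were handled is not given, so these regions do not exclude a difference in sex. A greater number of peaks does not account for the Y or X peaks. With equal peak numbers Y stood at 2.52 times the mean of the other libraries and X outside 120 to 123 Mb at 0.831 times, against 0.975 to 1.06 times on the autosomes. The loss at X 120 to 123 Mb is a separate matter: 98.4% of the regions that the other 6 libraries called there were called in neither Smc3-deleted Flt3-ITD library, against 6.49% on the rest of X (68 regions, with 8 at X 51 to 52 Mb and 20 at 53 to 54 Mb; 3.96% outside these) and 0.738% on autosomes. Calls at X 47 to 48 Mb ran the other way, with 21 and 20 regions in the Smc3-deleted Flt3-ITD libraries and 5 to 14 in each other library. A single X in place of a pair would lower X alike and does not account for the tract at 120 to 123 Mb, but stays open for the rest of X. Repeated sequence that was mapped or filtered differently and a difference in copy number between mouse strains are candidate explanations, and neither was tested. A tract with 8 such regions also lies on chromosome 3. It was seen before this comparison was set, and both explanations allow it, so it does not favour either. Sex and genotype cannot be separated in this design. Sex and a difference in mapping or filtering stay open for each comparison with this genotype.

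Of the 35 splits, only the real one by Flt3-ITD gave as many as 2318 regions, and the next gave 455. Only 3 of these splits keep the libraries of each genotype together, and libraries of a genotype are more alike. The Flt3-ITD count was the highest of these 3, which are too few to exclude chance at the level of genotypes. For Smc3 deletion (345 regions) 4 of the 35 splits gave as many, and for the interaction (451 regions) 3 did. The 35 splits include those by the other genotype contrasts, among them Flt3-ITD with 2318 regions. Neither share could therefore fall under 0.05, so this comparison cannot decide on chance for either. The highest split that mixes libraries of genotypes gave 455 regions. Peak number does not account for the Flt3-ITD count, since with equal peak numbers the count was 6.41 times that of the highest other split. That other split was the one by Smc3 deletion, with 362 regions. As the test for sex, the share of these regions on X and Y was 2.85%. The Y difference set Smc3-deleted Flt3-ITD apart from all other libraries, so regions that follow it could not meet the rule of this separation. The share also does not cover differences by sex on autosomes, so the test cannot decide on sex. An exchange of the Flt3-ITD and Smc3 del/+ labels stays open: under the descriptions the count for Flt3-ITD would be 345, and no value in the files tells which label is right. If the genotype labels hold, a response of chromatin to Flt3 signalling is a hypothesis for the 2318 regions that was not tested. Genes, motifs and cell type markers were not analysed, so the mix of cells in the c-Kit+ fraction is unknown. Read depth is unknown as well.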

How the results depend on the processing

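The score limit of exactly 1, absence within 1 kb and the removal of both Smc3-deleted Flt3-ITD libraries were chosen after seeing the data; the others were fixed before. Counts stayed within 1.5 times the reported value under autosomes only, an overlap of 50% and absence within 1 kb for all gained, lost and separating regions. Some call share differences moved beyond the spread of the libraries. With an overlap of 50% they went from 44.4 to 31.2 percentage points for Flt3-ITD gains and from -19.2 to -14.5 for Flt3-ITD losses. For Smc3 del/+ gains the difference went from 10.9 to 4.69. With absence within 1 kb it was 52.4 for Flt3-ITD gains and 15.1 for Smc3 del/+ gains. Under absence within 1 kb the separating counts were 1892 for Flt3-ITD, 237 for Smc3 deletion and 328 for the interaction, and 24 of the 42 distinct named regions no longer passed.

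With the upper 50% of each list by score, Smc3 del/+ lost 2971 regions, Flt3-ITD gained 1323 and lost 2051, and Smc3-deleted Flt3-ITD gained 5536 and lost 1937 against control, 5077 and 1122 against Flt3-ITD, and 7688 and 2056 against Smc3 del/+. Flt3-ITD separated 803 and the interaction 276. Call share differences shrank from -19.2 to -0.926 percentage points for regions lost in Flt3-ITD and from -28.8 to -7.49 for those lost in Smc3-deleted Flt3-ITD. Fewer peaks enter by construction. With a score of exactly 1, gains and losses were 395 and 2969 for Smc3 del/+, 805 and 1102 for Flt3-ITD, and for Smc3-deleted Flt3-ITD 4638 and 808 against control, 4440 and 500 against Flt3-ITD, and 7727 and 507 against Smc3 del/+. Separating counts were 132 for Smc3 deletion, 438 for Flt3-ITD and 298 for the interaction. Differences in call share reversed, to 31.6 and 13.6 percentage points, for regions lost in Flt3-ITD and in Smc3-deleted Flt3-ITD; the cause was not tested.

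With equal peak numbers, Smc3 del/+ gained 2771, Flt3-ITD gained 3315 and lost 3900, and Smc3-deleted Flt3-ITD gained 6430 against control, gained 4216 and lost 3455 against Flt3-ITD, and gained 7612 against Smc3 del/+. The interaction separated 292. Removing the weakest peaks of the longest lists does this by construction. The interaction in bases covered reversed from 2.03 Mb (exact p = 0.286) to -3.73 Mb (exact p = 0.0286), because narrower peaks then cover fewer bases. The call shares of Smc3 del/+ regions reversed to -3.54 and -5.34 percentage points, and those of Flt3-ITD gains and losses moved to 27.5 and -37.9.

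Under the groups of the descriptions, Smc3-deleted Flt3-ITD gained 14087 and lost 4249 against Flt3-ITD, and gained 9018 and lost 2055 against Smc3 del/+; Smc3 deletion separated 2318 and Flt3-ITD 345. Call share differences reversed to 10.3, -19.2, -17.2 and 28.8 percentage points. The names trade places by construction. Without both Smc3-deleted Flt3-ITD libraries the similarity difference was 0.0313 (exact p = 0.0667, the smallest possible), and 2972, 3839 and 1924 regions separated for Smc3 deletion, Flt3-ITD and the interaction, with fewer libraries to satisfy.

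Leaving out each replicate in turn raises counts, since fewer libraries must satisfy the rule. Gains and losses ran from 3035 to 6664 and 8457 to 13706 for Smc3 del/+, and from 4306 to 8662 and 7389 to 14081 for Flt3-ITD. For Smc3-deleted Flt3-ITD they ran from 12579 to 18654 and 6176 to 12020 against control, 12864 to 17727 and 3480 to 6430 against Flt3-ITD, and 18406 to 23320 and 5630 to 9258 against Smc3 del/+. Separating counts ran from 583 to 725 for Smc3 deletion, 2623 to 3689 for Flt3-ITD, which had the most regions of all splits each time, and 672 to 1256 for the interaction. The difference in peak number ran from 889 to 7137 for Smc3 deletion and 4398 to 9891 for Flt3-ITD. The interaction ran from 9025 to 14332, and in bases covered from 1.13 to 3.69 Mb, and both had an exact p of 0.0286 without control replicate 2. The similarity difference kept its exact p of 0.00952 in the removals of a single library.

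Replicate numbers do not pair the libraries: differences between replicates 1 and 2 correlated by -0.0103 to 0.00806 across genotypes. With permutation within the replicate block, whose smallest p is 0.0556, the interaction in peak number stayed at 10898 (exact p = 0.0556), and gained and lost counts are the same by construction. Flt3-ITD again gave the most regions, 2318, of the 18 splits that keep the block, with 451 as the next. Promoter shares, gene lists, motifs and the read count model, with their alternatives, were not run. Read depth is unknown and limits every absence.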

Other observations

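All tests in this part were chosen after the results were seen.

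Autosomal regions that changed in the single genotypes passed the test for gathering in 12 windows of 1 Mb. In Flt3-ITD, 12 of the 33 testable regions at chromosome 2, 169 to 170 Mb, were gained (36.4%, hypergeometric p after Benjamini-Hochberg adjustment 1.7e-05). Gains also gathered at chromosome 1, 122 to 123 Mb (7 of 18), chromosome 7, 74 to 75 Mb (9 of 37), chromosome 8, 33 to 34 Mb (6 of 15), and chromosome 16, 88 to 89 Mb (3 of 3). Flt3-ITD losses gathered at chromosome 1, 131 to 132 Mb (4 of 4) and 176 to 177 Mb (6 of 10), chromosome 3, 148 to 149 Mb (11 of 35), and chromosome 12, 84 to 85 Mb (7 of 15). Smc3 del/+ losses gathered at chromosome 2, 27 to 28 Mb (12 of 31), chromosome 10, 20 to 21 Mb (18 of 68), and chromosome 1, 40 to 41 Mb (16 of 59). No window passed for Smc3 del/+ gains.

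No autosomal window passed in any other split of the same libraries, but those splits hold fewer regions, so each set was thinned at random to the size of the largest of them, in 100 draws. No window was left in 5 of the draws for Flt3-ITD gains, 83 for Flt3-ITD losses and 66 for Smc3 del/+ losses, so at equal size the losses are not set apart from the other splits. The gains lie at the bound of 5 draws, too close to decide with this number of draws, and chance placement stays open for all 3 sets. Among regions lost in Smc3-deleted Flt3-ITD against control, 18 windows passed over all chromosomes and 5 with autosomes alone, each against at most 1 in the other splits. Autosomal windows passed in the other sets of this genotype too, which were not thinned. Against control 20 passed for gains, with at most 1 in the other splits. Against Flt3-ITD 11 passed for gains and 3 for losses, again with at most 1. Against Smc3 del/+ 14 passed for gains and 22 for losses, with 0 in the other splits. Thinned to the size of the other splits, the losses against control kept more than 1 window in every draw (5 to 13 windows, with 0 of 100 draws giving no more). This thinning covered all chromosomes. The windows with the lowest p lay at X 120 to 123 Mb, a tract chosen from these same values. The draws therefore restate that tract and do not decide on placement by chance elsewhere. Autosomal losses alone were not thinned. The window at chromosome 3, 25 to 26 Mb, lost 11 of 12 testable regions and holds the tract on that chromosome.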
